A study of Homo sapiens with 15 samples.

How the data were processed

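RNA of human peripheral blood mononuclear cells (PBMC) was sequenced in 15 samples: 5 kept in media, 5 infected with the RH strain of Toxoplasma gondii and 5 infected with the Pru strain. The authors deposited 12 tables of Cuffdiff comparisons. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.0 to hg38 and quantified with Cuffdiff 2.2.1. The deposited values are FPKM (fragments scaled to transcript length and to the number of mapped fragments), which the authors' software scaled within each table. The deposited q values are p-values adjusted for a false discovery rate by the authors' Cuffdiff run, within each table. No read counts were used here and the values fall on no grid of whole reads, so the depth of a library is unknown and no counting interval can be given. The total of all FPKM of a library lay between 901376 and 1114020.

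The table named for replicate 4 of RH was byte for byte the same as another table of replicate 5, and its own sample names say replicate 5. It was not used, which leaves 4 RH replicates (1, 2, 3 and 5), 5 Pru replicates, 5 media replicates and 14 libraries with values. The sample names inside the table of Pru replicate 4 carry no number, and its place rests on the name of the table and on the sample descriptions that list it. Of the 11 tables used, 9 hold libraries of a single replicate number: 4 of these hold an infected library with its media library, and 5 hold the RH, Pru and media libraries together, all of replicates 1, 3 and 5. The other 2 compare a strain with media in groups pooled by the authors, and which libraries went into them is not stated. In replicates 1, 3 and 5 the media values were identical in the tables of both strains. In replicate 2 they differed by a constant factor of 1.01, so each ratio was taken within its own table.

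Each table lists 197597 UCSC transcripts by position without gene symbols, and transcripts that overlap share a position range, called a locus here. Loci on the primary chromosomes were matched by position to GENCODE 44 genes of the same build, hg38, with a minimum overlap fraction of 0.5. The FPKM of all transcripts of a locus were summed. Transcripts on alternate or unplaced sequences (15289) were left out. Of 26121 loci used, 12894 held a single coding gene, 2703 several coding genes, 2438 a single noncoding gene, and 8086 had no name. Loci of several coding genes took 34.0% to 37.9% of the FPKM of a library and are named by all their genes, such as ART3/CXCL10/CXCL11. A small RNA gene lay within 5553 loci. The FPKM of very short transcripts are inflated, and named genes with such a locus are pointed out.

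The main fits used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Log2 ratios of infected over media were taken within each replicate, which makes the replicate number a block, and their mean was tested with eBayes with a trend on the mean level. Loci needed a mean of at least 1 FPKM and no failed estimate. P-values were adjusted with the Benjamini-Hochberg method over all loci tested, with a threshold of 0.05. RH was compared with Pru by the differences of their log2 ratios within replicates 1, 2, 3 and 5. The p-values measure the spread of these within-replicate ratios, or of their differences, between replicate numbers. The labels do not say whether a number stands for a donor or for another unit. Whether numbers pair the samples was checked on loci left after the group means were removed: libraries of the same number correlated at r = 0.17 to 0.469 across genes, and libraries of other numbers at -0.34 to 0.087. S100A11 and CCL2 were also tested with an exact sign-flip permutation over replicates, two-sided.

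Before the data were examined, 20 gene lists and 11 lists of cell type markers were fixed, 641 genes in all. A list was tested where at least 3 of its loci passed the filter, and a locus of several genes counted only if all its genes were in the list. Of the 641 genes, 459 had a locus of their own, 21 shared one with members of the same list, 159 shared one with other genes and 2 were absent. On the primary chromosomes the values of 22 list genes were 0 in every library. TNF, CCL3, CCL5, CCL18, IRF7, TAP1, PSMB8, PSMB9, HSPA1A and, of MHC class II, HLA-DPA1, HLA-DPB1 and HLA-DOA were among them. Any transcripts of these genes on the alternate or unplaced sequences left out were not counted, so nothing can be said of them. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry (statmod 1.5.0). Fry tests whether the genes of a list move, on balance, one way and does not compare the list with other genes. List p-values were adjusted over the lists of a comparison.

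The rule for named genes was also fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among loci of a single symbol past the threshold, with the same direction in every replicate and a mean of at least 5 FPKM in the higher group. It adds 16 fixed genes and, from each list, the 4 members past the threshold with the largest change. It names 96 loci for RH against media, 114 for Pru against media and 26 for RH against Pru. Other genes given by name were chosen after their values were seen, and the text says so.

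The alternatives were pseudocounts of 0.1 and 0.5 FPKM, no filter on low values, a filter at 5 FPKM, ratios centred on their median, quantile normalization, no intensity trend, robust eBayes, no replicate block, failed estimates treated as missing, and leaving out each replicate in turn. Leaving out loci with a small RNA gene, keeping only loci of a single coding gene, and testing the lists without replicate 1 or with centred ratios were added after seeing the data. The procedure was tested on simulated data with 200 changed loci. At a log2 size of 1 it recovered 27% of them in the RH design, 86% in the Pru design and 61% in the comparison of the strains, and at a log2 size of 2 it recovered 93%, 97% and 99%, with 6 to 9 false calls. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.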

Results

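The series measured the mRNA of human peripheral blood mononuclear cells, a mix of lymphocytes, monocytes and a few dendritic cells, after culture in media or with the intracellular parasite Toxoplasma gondii. RH and Pru are laboratory strains of the parasite, of the type I and type II lineages. Values are available for 5 media libraries, 4 RH libraries (replicates 1, 2, 3 and 5) and 5 Pru libraries, as FPKM summed per locus on genome build hg38. The depth of the libraries is unknown. All changes below are log2 ratios of FPKM + 1 within a replicate, with limma's moderated standard error (SE), which draws on the spread of other loci and can be smaller than the SE over replicates. Adjusted p-values are those of limma.

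RH against media asks how infection with the type I strain changed the transcripts of PBMC. The largest rise was in CCL17 (chromosome 16, 57404767 to 57416062), a chemokine that attracts T cells through the receptor CCR4, which rose by 10.03 ± 0.39 (SE, n = 4, adjusted p = 0.00177, higher in 4 of 4 replicates), from a mean of 0.329 FPKM in media to 1600 FPKM. CCL22, its neighbour and a ligand of the same receptor, rose by 6.10 ± 0.38, ALOX15, a lipoxygenase, by 5.78 ± 0.64, and MAOA, monoamine oxidase A, by 5.65 ± 0.22. CCL26, the chemokine eotaxin-3, was listed at 0 in the 4 media libraries and at 6.54 to 101 FPKM in the RH libraries. The other large rises were in C17orf58 (5.66), the monocyte chemoattractant CCL7 (4.59), the signalling ligand WNT5A (4.51), the replication licensing factor CDT1 (4.43) and the interleukin-1 receptor antagonist IL1RN (4.33). FCN1, a lectin of monocytes, showed the largest fall and fell by 5.23 ± 0.29 (SE, n = 4, adjusted p = 0.00276, lower in 4 of 4 replicates), from 984 to 29.6 FPKM.

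The other large falls in RH included 3 monocyte markers of the fixed list, CD14, CCR2 and LYZ. CLEC10A, a lectin of dendritic cells and macrophages, changed by -4.85, CD14, the lipopolysaccharide co-receptor, by -4.38, CCR2, the receptor for CCL2, by -4.29, and LYZ, lysozyme, by -4.13, from 12920 to 1409 FPKM. GAPT (-4.68), PID1 (-4.67), CD101 (-4.46), FUCA1 (-4.38) and CD9 (-3.95) also fell, and the loci of PID1 and CD9 hold a small RNA gene. Of 12 monocyte markers tested 9 fell, none rose, and the median change was -2.69 (adjusted p = 4.08e-06, and 0.244 with an estimated correlation). Monocyte markers that did not pass were CLEC7A (-0.34), MARCO (-0.28) and CD93 (1.11). Of 7 neutrophil markers 3 fell, with CSF3R, the receptor for granulocyte colony-stimulating factor, at -2.65 (list adjusted p = 0.00233, and 0.313 with an estimated correlation). Of 17 T cell markers 4 fell and IL7R rose (0.75), with a median of -0.43 (adjusted p = 0.00493, and 0.455 with an estimated correlation), and CD4, which monocytes also express, fell by 1.63.

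Inflammatory genes rose in RH. The chemokine list and the interleukin-4 and STAT6 list share members, among them the CCR4 ligands CCL17 and CCL22 and also CCL26. The mean log2 ratio in replicate 1 was 3.53 for chemokines (1.32 to 2.51 in the other replicates) and 2.07 for the NF-kB list (0.52 to 0.99). It was 1.83 for cytokines and growth factors (1.43 to 1.51), 1.79 for the interleukin-4 and STAT6 list (0.93 to 2.25) and 0.825 for immediate-early genes (0.77 to 1.12). Of 23 chemokine loci 12 rose and 1 fell, with a median of 2.52 (adjusted p = 0.000282, and 0.425 with an estimated correlation). Of 21 loci of inflammatory cytokines and growth factors 12 rose and 1 fell, with oncostatin M (OSM) at 3.79, the growth factor CSF2 at 3.67 and the activin subunit INHBA at 3.57 (list adjusted p = 4.91e-05, and 0.244 with an estimated correlation). IL1B rose by 3.46 ± 0.26 and IL6 by 2.31 ± 0.28. Of 27 loci of the NF-kB list 15 rose, among them TNIP3 (2.90, a locus with a small RNA gene), BCL2A1 (2.35) and TRAF1 (2.16), and none fell (adjusted p = 1.25e-06, and 0.425 with an estimated correlation). Of 25 loci of the interleukin-4 and STAT6 list 11 rose and 2 fell, with a median of 1.14 and a mean of 1.77 (adjusted p = 0.000811, and 0.448 with an estimated correlation). Of 27 immediate-early genes 13 rose and 1 fell, with FOSL1 at 2.87 and FOS at -2.37 (adjusted p = 0.000301, and 0.313 with an estimated correlation). Adjusted over the list alone, 13 chemokine loci rose and 3 fell, 14 cytokine loci rose and 1 fell, 19 NF-kB loci rose, 12 STAT6 loci rose and 2 fell, and 16 immediate-early loci rose and 3 fell.

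Genes of growth and biosynthesis rose in RH as well, but little in replicate 1. The mean log2 ratio in replicate 1 was 0.31 for ribosome biogenesis (1.62 to 1.77 in the other replicates), 0.16 for the cell cycle (1.63 to 1.66) and 0.26 for cholesterol synthesis (1.42 to 1.69). Fibroblast markers, a list that did not pass, had -0.16 in replicate 1 and 0.47 to 0.60 in the others. Of 17 loci of ribosome biogenesis 12 rose and none fell, with a median of 1.26, DDX21 at 1.88 and NOLC1 at 1.80 (list adjusted p = 1.25e-06, and 0.425 with an estimated correlation). Of 11 cell cycle loci 5 rose, led by the replication helicase subunit MCM4 at 3.13 ± 0.62, with 0.617 in replicate 1 (list adjusted p = 0.000282, and 0.425 with an estimated correlation). Of 19 loci of cholesterol and fatty acid synthesis 6 rose, led by the desaturase SCD at 3.35 ± 0.73, with 0.46 in replicate 1 (list adjusted p = 4.91e-05, and 0.425 with an estimated correlation). Of 17 loci of the stress response list 9 rose, and the largest, CHAC1 (3.80), PHGDH (3.55), SLC7A5 (3.46, a locus with a small RNA gene) and PSAT1 (3.19), are targets of ATF4 that take part in glutathione breakdown, serine synthesis and amino acid uptake (list adjusted p = 0.00132, and 0.313 with an estimated correlation). Of 19 loci of glycolysis and hypoxia 9 rose, with VEGFA at 2.74 and LDHA at 1.89 (list adjusted p = 0.00167, and 0.425 with an estimated correlation). Of 7 loci of MHC class II antigen presentation 5 fell, with the protease CTSS at -2.46 and CD74 at -1.31, and the list mean was -0.24 in replicate 1 and at or below -1.65 in the others (list adjusted p = 0.000454, and 0.425 with an estimated correlation). Adjusted over the list alone, 17 ribosome biogenesis, 9 cell cycle, 11 cholesterol, 11 stress response and 9 glycolysis loci rose and 7 MHC class II loci fell.

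In RH against media 993 of 9794 loci were higher and 874 lower, of which 621 and 502 changed by at least 2-fold. With quantile normalization 871 were higher and 1018 lower. Replicate 1 stood apart from the others: without it, 4189 loci passed, 1859 of them among the 1867 called with it. Without replicate 2, 3 or 5, 245, 124 and 68 loci passed, and with no filter on low values 806. Of the 87 named genes past the threshold, 86, 37, 26 and 19 stayed past it without replicate 1, 2, 3 and 5.

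Interferon-stimulated genes did not move together over the RH replicates. The mean log2 ratio of 27 type I interferon-stimulated loci was 2.63 in replicate 1 and -0.08, -1.80 and -0.55 in replicates 2, 3 and 5, and that of 15 interferon-gamma response loci was 1.95 in replicate 1 and -0.58, -0.75 and -0.63 in the others. Over all replicates 1 locus of each list passed, LAMP3 (2.76) and the checkpoint ligand CD274 (2.06), and neither list passed (adjusted p = 0.998 and 0.763). Without replicate 1, both lists were lower than other genes, with medians of -0.85 and -0.67 and an adjusted p of 0.00268 each, and of 0.561 and 0.4 with an estimated correlation. The locus of CXCL10 with ART3 and CXCL11 changed by 0.90 ± 1.31 (adjusted p = 0.646), with 6.29 in replicate 1, and by -0.90 without it.

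**Figure D1:**
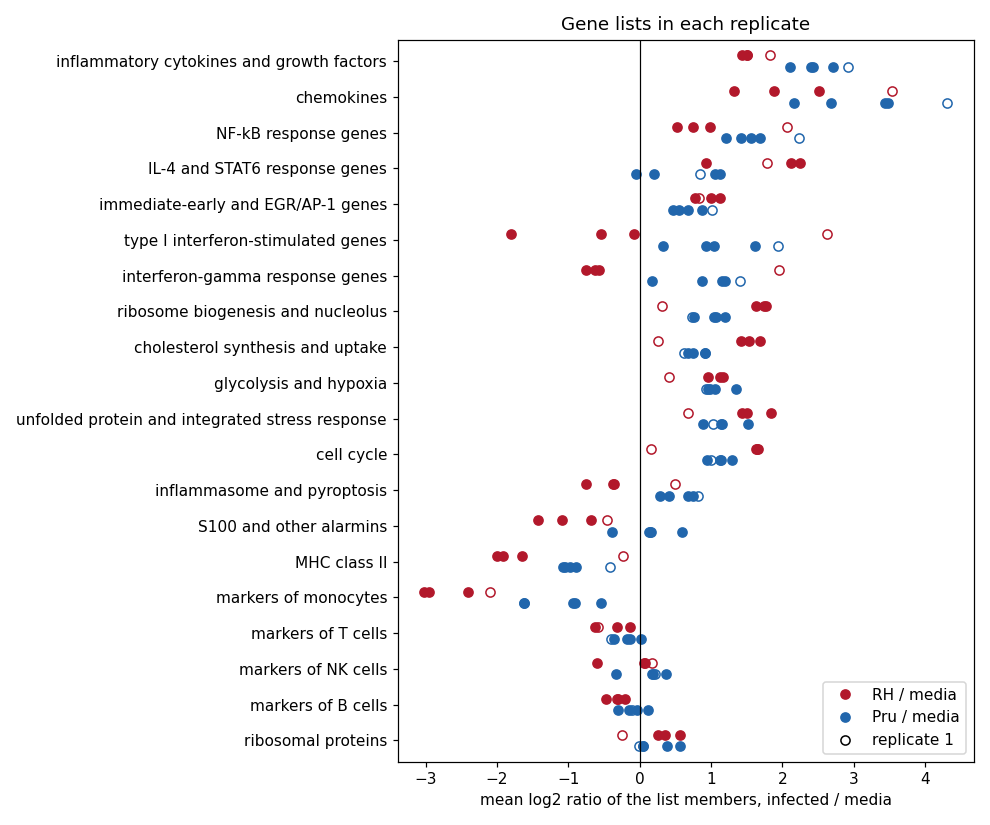
Mean log2 ratio of infected over media (horizontal axis) of the measured members of 20 gene lists and marker lists (vertical axis), a point per replicate, RH in red and Pru in blue, with open symbols for replicate 1. The type I interferon-stimulated genes of RH lie at 2.63 in replicate 1 and at or below -0.08 in the other replicates, and the monocyte markers of RH lie between -3.02 and -2.10.

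Pru against media asks the same of the type II strain. The largest rises were mostly in chemokines and cytokines: the neutrophil chemokine CXCL1 (chromosome 4, 73869393 to 73871242) rose by 6.36 ± 0.49 (SE, n = 5, adjusted p = 0.000162, higher in 5 of 5 replicates), from 8.41 to 668 FPKM. The chemokine CCL8 rose by 6.29 ± 0.54, the cytokine IL6 by 6.26 ± 0.31, CCL7 by 6.23 ± 0.63 and IL1B by 5.99 ± 0.28, from 18.8 to 1227 FPKM. ACOD1, the enzyme that makes itaconate, rose by 5.77, the neutrophil chemokine CXCL8 by 5.72, IL1A by 5.17, CCL19 by 5.12 and CSF2 by 4.93. The largest falls were in CLEC10A (-5.31 ± 0.19, n = 5), FCN1 (-4.68), the lysosomal fucosidase FUCA1 (-4.30), CD9 (-4.04), CD101 (-3.97), GAPT (-3.80), RNASE6 (-3.79), PRAM1 (-3.77), PRUNE2 (-3.72) and GPNMB (-3.72). The loci of CD9 and PRUNE2 hold a small RNA gene.

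The inflammatory lists rose in Pru. Of 24 loci of cytokines and growth factors 21 rose and none fell, with a median of 2.07 (adjusted p = 1.08e-10, and 0.237 with an estimated correlation). Of 27 NF-kB loci 23 rose and none fell, with the prostaglandin synthase PTGS2 at 3.72 and TNFAIP6 at 3.51, a locus with a small RNA gene (list adjusted p = 1.08e-10, and 0.329 with an estimated correlation). Of 23 chemokine loci 19 rose and 1 fell, with a median of 3.89 and CCL20, the ligand of CCR6, at 4.78 (list adjusted p = 3.96e-07, and 0.329 with an estimated correlation). Of 27 type I interferon-stimulated loci 21 rose and none fell, with CMPK2/RSAD2 at 2.27 and USP18 at 2.05 (list adjusted p = 6.82e-07, and 0.51 with an estimated correlation). Of 15 interferon-gamma response loci 10 rose and none fell, with GBP5 at 1.74 and GBP1 at 1.38 (list adjusted p = 0.000555, and 0.51 with an estimated correlation). The IDO1/IDO2 locus, of enzymes that break down tryptophan, rose by 2.82 ± 0.37, and the locus of CXCL10 by 2.03 ± 0.58 (higher in 4 of 5 replicates). Of 26 immediate-early loci 16 rose and 2 fell (adjusted p = 0.000688, and 0.329 with an estimated correlation). Adjusted over the list alone, 22 cytokine, 25 NF-kB, 20 chemokine, 23 type I interferon, 10 interferon-gamma and 18 immediate-early loci rose, and 3 chemokine, 1 type I interferon and 2 immediate-early loci fell.

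Growth and biosynthesis genes rose in Pru too. All 13 cell cycle loci tested rose, with MCM4 at 2.73 ± 0.17 (list adjusted p = 2.16e-06, and 0.237 with an estimated correlation). Of 17 ribosome biogenesis loci 15 rose (adjusted p = 4.97e-07, and 0.329 with an estimated correlation), and of 19 cholesterol and fatty acid loci 13 rose, with SCD at 2.57 (adjusted p = 0.000265, and 0.329 with an estimated correlation). Of 20 loci of glycolysis and hypoxia 13 rose and 1 fell, with carbonic anhydrase CA12 at 3.47 (list adjusted p = 4.49e-05, and 0.329 with an estimated correlation). Of 17 stress response loci 12 rose and 1 fell, again led by CHAC1 (3.47) and PHGDH (3.11) (list adjusted p = 0.000342, and 0.329 with an estimated correlation). Of 7 MHC class II loci 6 fell, with CTSS at -1.34 (list adjusted p = 0.000797, and 0.329 with an estimated correlation). Of 12 monocyte markers 7 fell and 2 rose, CD93 (2.82) and the scavenger receptor MARCO (1.87), which is outside the naming rule and was chosen after its values were seen. The median of the monocyte markers was -1.14 (adjusted p = 0.0043, and 0.395 with an estimated correlation). Of 6 neutrophil markers 4 fell (adjusted p = 0.0358, and 0.409 with an estimated correlation). Adjusted over the list alone, 13 cell cycle, 17 ribosome biogenesis, 14 cholesterol, 13 glycolysis and 12 stress response loci rose and 6 MHC class II loci fell.

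In Pru against media 2147 of 9740 loci were higher and 1782 lower, of which 693 and 491 changed by at least 2-fold. The majority is not stable: 54.6% of the called loci were higher, against 47.2% with quantile normalization and 49.0% without the replicate block. Of the 113 named genes past the threshold, between 107 and 111 stayed past it when a replicate was left out.

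RH against Pru asks whether the strains changed PBMC differently, from the 4 replicates that have both. CCL17 was 5.71 ± 0.38 higher in RH than in Pru (SE, n = 4, adjusted p = 0.0216, higher in 4 of 4 replicates), with means of 1600 and 47.6 FPKM, ALOX15 was 5.41 ± 0.33 higher (110 against 0.859 FPKM) and MAOA 1.81 ± 0.14 higher. The neutrophil chemokines CXCL1 (-3.40 ± 0.19), CXCL3 (-2.90 ± 0.25), CXCL2 (-2.79 ± 0.14) and CXCL8 (-2.58 ± 0.11) were lower in RH than in Pru, each in 4 of 4 replicates. So were PTGS2 (-2.68), CCL19 (-2.40), the monocyte receptors CD14 (-3.05) and TREM1 (-1.68), the membrane glycoprotein PDPN (-2.73) and PID1 (-3.48), whose locus holds a small RNA gene. IL6 lay -3.71 ± 0.41 lower in 4 of 4 replicates and did not pass (adjusted p = 0.0691), and IL1B differed by -2.43 ± 0.38 (adjusted p = 0.162).

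Between the strains 3 loci of 9801 were higher in RH and 12 lower, and 1448 had an unadjusted p under 0.05. Without replicate 1, 1060 were higher and 1165 lower, the 15 loci of the full set among them. Without replicate 2 or 3 limma called 0 loci (640 and 545 at an unadjusted p under 0.05), and without replicate 5 it called 1 (600 unadjusted). With no filter on low values 1 locus passed, with loci of small RNA genes left out 25, and with loci of a single coding gene only 28.

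The lists that differed between the strains fell in 2 sets. In RH, 24 loci of the STAT6 list had a median difference of 0.44 and a mean of 1.08 above Pru, with 3 higher (adjusted p = 1.75e-05, and 0.352 with an estimated correlation). Ribosome biogenesis (17 loci, none called) lay 0.44 higher (adjusted p = 0.00019, and 0.468 with an estimated correlation) and cholesterol synthesis (19 loci, none called) 0.40 higher (adjusted p = 0.00041, and 0.465 with an estimated correlation). In the other direction, 23 chemokine loci had a median difference of -1.94, with 1 higher and 5 lower (adjusted p = 2.64e-06, and 0.352 with an estimated correlation), 23 cytokine loci -0.96, with none called (adjusted p = 2.14e-06, and 0.352 with an estimated correlation), and 27 NF-kB loci -0.37, with 1 lower (adjusted p = 2.64e-06, and 0.352 with an estimated correlation). Type I interferon-stimulated genes lay at -1.34 (adjusted p = 4.82e-08, and 0.465 with an estimated correlation) and interferon-gamma response genes at -1.12 (adjusted p = 2.77e-06, and 0.465 with an estimated correlation), with none called. Replicate 1 went the other way in 4 of these lists: its type I list lay 0.69 above Pru, and its mean log2 ratios in RH and Pru were 1.95 and 1.40 for interferon-gamma genes, 0.31 and 0.73 for ribosome biogenesis and 0.26 and 0.62 for cholesterol synthesis. Monocyte markers lay at -1.61, with CD14 lower (adjusted p = 2.27e-06, and 0.369 with an estimated correlation). Adjusted over the list alone, 7 STAT6, 2 chemokine and 1 cytokine loci were higher and 13 chemokine, 12 cytokine, 6 NF-kB and 6 monocyte loci lower.

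S100A11 encodes an alarmin, a protein that signals damage when released from cells, and CCL2 encodes a chemoattractant for monocytes. The series title names S100A11 and a chemokine response. The S100A11 locus (chromosome 1, 151994531 to 152047907) gave 1222 ± 268 FPKM in media and 842 ± 446 FPKM in RH (SD, n = 4). Its log2 change in RH was -0.64 ± 0.33 (moderated SE, with an SD of 0.84 over replicates, adjusted p = 0.219, lower in 3 of 4 replicates), and the exact sign-flip permutation gave p = 0.25, where 0.125 is the smallest possible with 4 replicates. Without replicate 1 the change was -1.04 (adjusted p = 0.00572). In Pru the locus gave 1259 ± 181 FPKM against 1353 ± 382 in media (SD, n = 5), a log2 change of -0.07 ± 0.14 (SD of 0.30 over replicates, adjusted p = 0.708, lower in 3 of 5 replicates, exact p = 0.625). RH and Pru differed by -0.64 ± 0.29 (SD of 0.71 over replicates, adjusted p = 0.355, exact p = 0.25) and by -0.996 without replicate 1 (adjusted p = 0.00793).

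The CCL2 locus (chromosome 17, 34255218 to 34257203) gave 5221 ± 2017 FPKM in Pru against 345 ± 302 in media (SD, n = 5). It rose in Pru by 4.46 ± 0.53 (moderated SE, with an SD of 1.59 over replicates, adjusted p = 0.000811, higher in 5 of 5 replicates), and the exact sign-flip permutation gave p = 0.062, the smallest possible with 5 replicates. In RH it gave 1417 ± 1538 FPKM against 273 ± 295 in media (SD, n = 4), a log2 change of 2.52 ± 1.01 that did not pass (SD of 2.76 over replicates, adjusted p = 0.129, higher in 3 of 4 replicates, exact p = 0.25). Without replicate 1, which had 3719 FPKM in RH, the change was 1.29 (adjusted p = 0.118). CCL2 was lower in RH than in Pru in 4 of 4 replicates, by -2.12 ± 0.47 (SD of 1.24 over replicates, adjusted p = 0.251, exact p = 0.125, the smallest possible), and by -2.72 without replicate 1 (adjusted p = 0.00653).

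**Figure D2:**
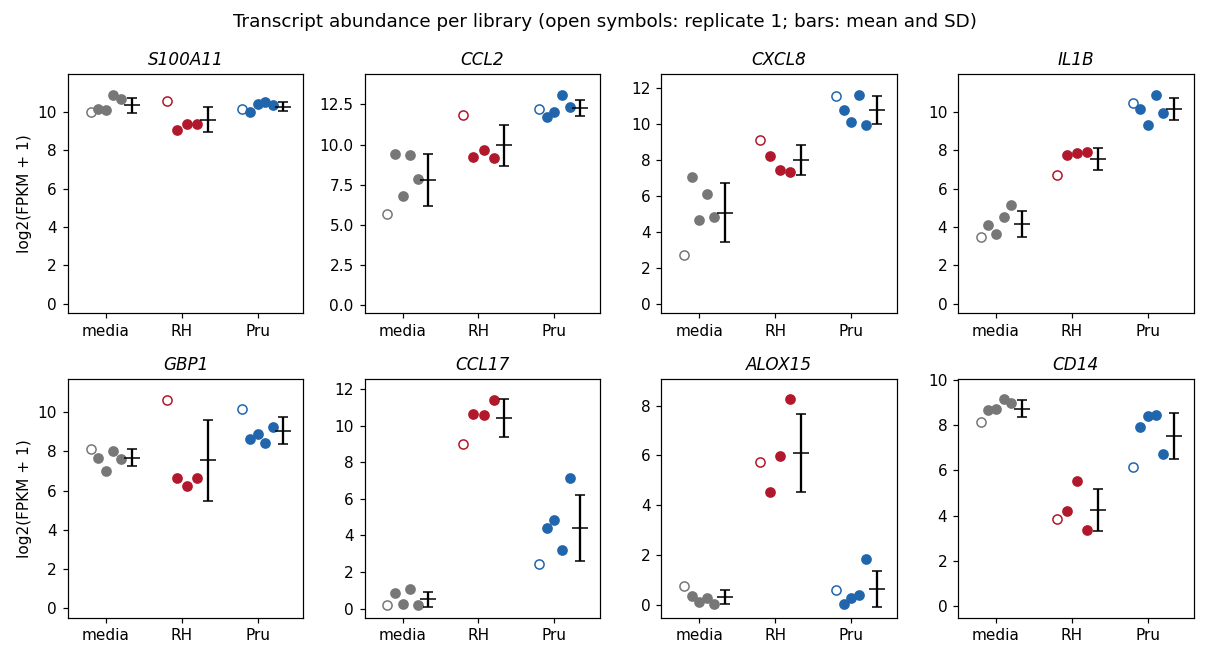
Transcript abundance as log2(FPKM + 1) on the vertical axis, a point per library of media, RH and Pru, for 8 genes, with bars for the mean and SD of each group and open symbols for replicate 1. S100A11 in RH lies at 536 to 673 FPKM in replicates 2, 3 and 5 and at 1505 FPKM in replicate 1, and CCL17 lies at 505 FPKM or above in all 4 RH libraries.

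Of the other fixed genes, CCL8 changed in RH by 4.36 ± 1.21 (adjusted p = 0.057, higher in 4 of 4 replicates), with 9.32 in replicate 1 and a change of 2.71 without it, and CXCL8 rose by 3.19 ± 0.83 (adjusted p = 0.0487, higher in 4 of 4), and by 2.12 without replicate 1. CCL20 rose by 2.94 ± 0.28 in RH. CASP1, the inflammasome protease, changed by -1.31 ± 0.46 in RH (adjusted p = 0.0993). It was at 284 FPKM in RH replicate 1, above its media library at 204 FPKM, and at 47.7 to 65.1 FPKM in the other RH libraries. In Pru it rose by 0.39 ± 0.11 (adjusted p = 0.0227, higher in 5 of 5). IRF1, whose locus holds a small RNA gene, changed by -0.17 ± 0.43 in RH (-0.72 without replicate 1) and rose by 0.68 ± 0.20 in Pru. GBP1 changed by -0.06 ± 0.64 in RH (-0.92 without replicate 1), and IL12B, whose locus holds a small RNA gene, by 1.44 ± 0.71 in RH (adjusted p = 0.196, with 4.17 in replicate 1 and -0.12 to 1.23 in the others), rising by 1.83 ± 0.49 in Pru. The IDO1/IDO2 locus changed by 0.89 ± 1.08 in RH (adjusted p = 0.58), and by -0.57 without replicate 1. AGER, a receptor for S100 proteins, was listed at 0 in every media and RH library and at most at 0.185 FPKM in Pru. It did not pass the filter on low values, and TNF was at 0 in every library. The values of both leave out alternate and unplaced sequences, so nothing can be said of either gene.

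The responses to the strains were similar in direction. Across 9610 loci tested in both, the log2 changes correlated at r = 0.849 over genes, which are not independent replicates, and 82.7% had the same sign. Sharing media libraries alone gave a mean r of 0.443 and 64.7% in 20 simulations of unchanged groups. With RH and Pru changes taken from different replicates, r was between 0.661 and 0.8. Of the called loci 866 were higher and 777 lower in both, against 211 and 162 for independent calls, and 1 changed in opposite directions.

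The authors' pooled tables, whose libraries are not stated, called 1014 transcripts for RH (669 higher, 345 lower) and 207 for Pru (195 higher, 12 lower). Of the loci of the RH transcripts called higher, 637 were tested here and 420 were called higher, and of 328 called lower 273 were called lower. For Pru the counts were 187 of 188 and 11 of 12. There, 1 of 4 CCL2 transcripts was called in Pru (q = 0.0189) and 0 of 4 in RH, and 0 of 3 S100A11 transcripts in either. The authors' tables of a single replicate called 109 transcripts for RH and 100 for Pru in replicate 1 and 0 in the other replicates. Whether these tables share their settings is not stated, so these counts are not compared.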

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

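All tests of explanations in this part, and the counts of other splits, were chosen or written down after the results were seen. The tests of explanations replaced earlier ones on fewer genes, which had been chosen for the pattern, and their bounds were set with the values known. The rules that pick samples and differences were fixed in advance.

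The RH library of replicate 1 lay far from the other RH libraries on several measures. The criterion was a gap to the nearest other sample that exceeds Dixon's 95% limit, and chance alone picks about 1 in 20 groups. Of 58 list means 7 met it, of 62 named genes 5, and of 3 groups of library totals 0. For RH, replicate 1 was picked by the mean log2 ratio of the cell cycle list (0.16), interferon-gamma response genes (1.95) and ribosome biogenesis (0.31), and by CDT1 (0.98), CCL8 (9.32), the locus of CXCL10 (6.29) and GBP1 (2.52). For Pru, replicate 1 was picked by MHC class II genes (-0.42), platelet markers (0.26) and CCL19 (6.94). Replicate 5 was picked by NK cell markers in RH (-0.61) and dendritic cell markers in Pru (-0.71). Ratios of replicate 1 also carry its media library, where CCL8 was at 2.305 FPKM, against 12.7 to 45.7 FPKM in the other media libraries. By levels, RH replicate 1 correlated at 0.875 to 0.887 with the other RH libraries, against 0.965 to 0.971 among those. Media replicate 1 correlated at 0.939 to 0.957 with the other media libraries, against 0.962 to 0.970 among those. For Pru replicate 1 these values were 0.945 to 0.950, against 0.957 to 0.967 among the other Pru libraries.

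Across 9610 loci the log2 ratios of RH replicate 1 correlated at 0.24 to 0.345 with those of the other RH replicates and at 0.472 to 0.589 with those of Pru replicates 2 to 5. With Pru replicate 1, which shares its media library, r was 0.826. The other pairs of RH and Pru with the same number, which also share media, had 0.712 to 0.752. The strain difference of replicate 1 correlated at -0.167 to -0.08 with those of the other replicates, which correlated at 0.596 to 0.617 with each other. A wrong label would put Pru-infected cells in the RH library of replicate 1, with or without an exchange. Genes that the other replicates called higher in RH argue against Pru-infected cells alone. Of 8 such genes of the STAT6 list, 5 lay above every Pru library in RH replicate 1. CCL17 was at 505 FPKM against at most 139 in Pru and ALOX15 at 51.7 against at most 2.63. All 8 but ALOX15 also lay below every other RH library, CCL17 against at least 1555 FPKM and MAOA at 58.4 against at least 101 FPKM. For CCL17, CCL26, MAOA and IL17RB the levels lay between those of Pru and of the other RH libraries, which is what a mix would give. CCL22 (749.6 FPKM against 689 to 1803 in Pru) and GATM lay within the range of Pru. RAMP1 (3.33 FPKM against at least 4.86 in Pru) lay below it. On the other side, of 2212 loci called between the strains without replicate 1, 27.2% had the same sign in replicate 1. A mix of RH-infected and Pru-infected cells would leave type I interferon-stimulated genes below Pru, as without replicate 1 (-2.01). In replicate 1 the mean of these 27 genes lay 0.69 above Pru. Dilution by uninfected cells would not raise them to 2.63 above media. Both values rest on 1 RH library. The SE of 0.06 for the first runs over genes and does not measure the spread between samples, so neither explanation is settled. A stronger interferon response in that sample, from a donor, a different infection or bystander cells, may account for the interferon genes and was not tested. Nor was it tested whether such a response bears on the low cell cycle (0.16) and ribosome biogenesis (0.31) means of RH replicate 1. In Pru the mean log2 ratio of the type I list was also highest in replicate 1, at 1.94 against 0.32 to 1.62 in the other Pru replicates.

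Monocyte markers fell in RH, with a mean log2 change of -2.62 and a median of -2.69. After centring each ratio on its median the mean was -2.64. The median change of all loci was already 0.03, so centring could move this mean little. The markers thus fell relative to the typical locus, and whether the authors' scaling of the tables was right was not tested. Fewer monocytes as the whole cause would lower all markers alike and raise those of other cells. The changes ran from FCN1 at -5.23 to CD93 at 1.11, with 6 of 12 markers more than 2 SE over replicates from the mean of the list (7 with the moderated SE), and the medians of T, NK and B cell markers were -0.43, -0.14 and -0.26. This does not settle it: fewer monocytes, as a part or the whole of the cause, and lower expression in monocytes after infection stay open.

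The STAT6 list and the chemokine list moved apart between the strains, although they share members such as CCL17, CCL22 and CCL26. Centring each replicate difference on its median left both list means nearly unchanged. The median difference of all loci was already 0.0001, so centring could move the means little. It cannot settle whether RH and Pru columns differ in scaling. The mean of RH minus Pru was 1.08 before and 1.11 ± 0.385 (SE over genes) after centring for the STAT6 list. For the chemokine list it was -0.96 before and -0.93 ± 0.49 after, within 2 SE of 0 both times. Fewer monocytes in RH than in Pru cannot be told apart from another source of the lower chemokine list: the list mean lay 0.49 ± 0.56 from that of the monocyte markers, while 4 of 12 of those markers lay more than 2 SE over replicates from their own mean. As background, the parasite kinase ROP16 of type I strains activates host STAT6 and the type II protein GRA15 activates host NF-kB, and a role of these strain differences here is a hypothesis that was not tested.

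The direct test between the strains picked 13 named genes. In RH, CCL17 (5.71), ALOX15 (5.41) and MAOA (1.81) were higher, and PID1 (-3.48), CXCL1 (-3.40), CD14 (-3.05), CXCL3 (-2.90), CXCL2 (-2.79), PDPN (-2.73), PTGS2 (-2.68), CXCL8 (-2.58), CCL19 (-2.40) and TREM1 (-1.68) lower than in Pru. The same test picked 15 lists. Their median differences were -1.94 for chemokines, 0.40 for cholesterol synthesis, 0.44 for the STAT6 list, -0.53 for the inflammasome, -0.96 for cytokines, -1.12 for interferon-gamma response genes, -2.38 for metallothioneins, -0.52 for MHC class II and -0.37 for NF-kB genes. They were 0.44 for ribosome biogenesis, -0.64 for S100 and other alarmins, -1.34 for type I interferon-stimulated genes, and -0.29, -1.61 and -0.18 for markers of B cells, monocytes and T cells. In replicate 1 the mean differences of both interferon lists, ribosome biogenesis, cholesterol synthesis and MHC class II had the opposite sign. With an estimated correlation none of the 15 lists passed (adjusted p of at least 0.352).

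Other splits of the same libraries were counted with the replicate numbers kept. For RH against media 1867 loci were called, and the highest of the other splits gave 3, so 1 of 35 splits, the real one, gave as many. Of these, 8 part RH and media within every replicate, the highest other of them gave 0, and 8 are too few for a share under 5%. For Pru against media 3929 loci were called, against at most 13 in the other splits drawn, so 1 of 100 gave as many. Of these, 14 part Pru and media within every replicate, the highest other of them gave 0, and they too are too few for a share under 5%. For RH against Pru 2 of 35 splits gave as many as the real 15, so chance cannot be excluded. The highest other split gave 934, and it is the split that exchanges RH and Pru in replicate 1 alone, which points to a structure of the samples. Among the 8 splits that part RH and Pru within every replicate, the real split and that one gave as many.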

How the results depend on the processing

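The settings that left out small RNA loci, kept loci of a single coding gene, or tested lists without replicate 1 or with centred ratios were chosen after seeing the data, and the others were planned. Counts within 1.5 times of the one reported are not listed except for the block. The cause of a change was not tested unless stated. Depth is unknown, so its limits cannot be given.

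Called loci in RH against media went from 1867 to 806 with no filter on low values, a setting that tests more loci, and to between 68 (without replicate 5) and 4189 (without replicate 1) with a replicate left out. Without the replicate block, which ignores the pairing, they were 1887, of which 1508 were shared. In Pru against media the count stayed between 2914 and 4104 under all settings, with 3284 without the block. In RH against Pru it went from 15 to 1 with no filter, 25 without small RNA loci, 28 with loci of a single coding gene, both of which test fewer loci, 11 without the block, of which 5 were shared, and between 0 (without replicate 2 or 3) and 2225 (without replicate 1). The correlation of both responses was 0.849, and 0.731 in the median with separate replicates.

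The log2 change of S100A11 ranged with a replicate left out from -1.04 (without replicate 1, then past the threshold) to -0.43 in RH, from -0.17 to 0.004 (without replicate 4) in Pru, and from -0.996 (without replicate 1, then past the threshold) to -0.50 between the strains. That of CCL2 between the strains ranged from -2.72 (without replicate 1, then past the threshold) to -1.76. CCL2 stayed past the threshold in Pru under all settings. In RH against media 4 loci that had not passed changed direction with a replicate left out: the locus of CXCL10 (-0.90 without replicate 1, up to 1.63), IDO1/IDO2 (-0.57 without replicate 1, up to 1.58), IRF1 (-0.72 to 0.12) and GBP1 (-0.92 to 0.25). Without replicate 1, the CXCL10 locus, IRF1 and GBP1 were called lower.

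With an estimated correlation in camera, 0 lists passed in any comparison, against 14, 14 and 15 with the preset one. Adjusted p in RH against media was 0.244 for cytokines and monocyte markers, 0.313 for immediate-early, stress response and neutrophil lists, 0.425 for cell cycle, chemokines, cholesterol synthesis, glycolysis, MHC class II, NF-kB and ribosome biogenesis, 0.448 for the STAT6 list and 0.455 for T cell markers. In Pru against media it was 0.237 for cell cycle and cytokines, 0.329 for chemokines, cholesterol synthesis, glycolysis, immediate-early genes, MHC class II, NF-kB, ribosome biogenesis and stress response, 0.395 for monocyte and 0.409 for neutrophil markers, and 0.51 for both interferon lists. In RH against Pru it was 0.352 for chemokines, the STAT6 list, cytokines, NF-kB, S100 genes and B cell markers, 0.369 for the inflammasome and monocyte and T cell markers, 0.386 for metallothioneins, 0.465 for cholesterol synthesis, both interferon lists and MHC class II, and 0.468 for ribosome biogenesis.

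With fry, 9 lists passed in RH against media, 18 in Pru against media and 7 in RH against Pru. Lists that changed sides in RH against media were B cell markers (adjusted p = 0.0417, now past), glycolysis (0.0516), cholesterol synthesis and ribosome biogenesis (0.0549 each), cell cycle (0.0602), and MHC class II and T cell markers (0.0669 each). In Pru against media, dendritic cell markers (0.00327), the STAT6 list (0.0178), platelet markers (0.0458) and metallothioneins (0.0463) now passed. In RH against Pru, monocyte markers (0.0796), the inflammasome and metallothioneins (0.113 each), MHC class II (0.243), interferon-gamma genes (0.261), cholesterol synthesis (0.265), type I interferon genes (0.276) and ribosome biogenesis (0.303) no longer passed. Without replicate 1, 21, 13 and 16 lists passed, and with centred ratios 14, 14 and 15.

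Over the named genes, settings other than leaving out a replicate kept side and direction in 1073 of 1130 cases for RH against media, 1323 of 1339 for Pru against media and 275 of 305 for RH against Pru, with no change of direction. With a replicate left out these were 191 of 382, 550 of 569 and 55 of 104. Quantile normalization, and likewise the fit without the block, moved the share of higher loci among those called in RH from 53.2% to 46.1%. In Pru it moved from 54.6% to 47.2%, and to 49.0% without the block. It turned the majority in both, but no scaling moved the median of all loci by more than 0.1 on the log2 scale.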

Other observations

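Several S100 genes of neutrophils and monocytes fell in RH, S100A8 and S100A9 among them, which also belong to the monocyte markers (median -2.69). S100A12 changed by -3.80 ± 0.25 (moderated SE, n = 4), S100A8 by -3.52 ± 0.67 and S100A9 by -2.50 ± 0.45, and of 11 loci of the S100 and alarmin list 5 fell and 2 rose, IL1A (1.98) among the latter (list adjusted p = 0.0622). In Pru, S100A12 changed by -1.72 and S100A8 by -1.26, S100P rose by 1.51, and 3 loci of 11 rose and 5 fell (list adjusted p = 0.535, with a median of -0.38 and a mean of 0.13). Of 14 inflammasome loci 2 rose and 4 fell in RH (adjusted p = 0.133), with NLRC4 at -2.67 and CARD16 at -1.92, and 6 rose and 4 fell in Pru (adjusted p = 0.685), with CASP5 at 2.19. In the STAT6 list 10 of 22 loci rose and 4 fell in Pru (adjusted p = 0.128), with CCL22 at 4.72 and MAOA at 3.85.

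Oxidative stress genes moved both ways: of 11 loci 3 rose and 2 fell in RH (adjusted p = 0.561), with thioredoxin TXN at 3.42 ± 0.29 and HMOX1 at -1.17, and 4 rose and 4 fell in Pru (adjusted p = 0.834), with TXN at 3.09. Metallothionein loci, 3 in number, had none past the threshold in RH (adjusted p = 0.883) and 2 higher in Pru, MT1M (2.70) and MT2A (1.21) (list adjusted p = 0.0975). Of 5 loci of cholesterol efflux 1 fell in RH (adjusted p = 0.998), APOC1/APOE at -0.62, and 2 rose and 1 fell in Pru (adjusted p = 0.352), with APOC1/APOE at -1.57 and the transporter ABCA1 at 1.01. Among dendritic cell markers BATF3, a transcription factor, rose by 3.93 in RH and 3.19 in Pru while FCER1A fell by 2.38 and 2.69, and neither list passed (8 loci each, adjusted p = 0.354 and 0.126). Ribosomal proteins (14 loci, 0 called, adjusted p = 0.173 and 0.128 in RH and Pru) and mitochondrially encoded genes (10 loci, 0 called, adjusted p = 0.139 and 0.107) did not pass.

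Markers of other cells gave these values. Of 12 B cell markers 2 fell in RH (list adjusted p = 0.0622), and 2 rose and 3 fell in Pru (0.759). Of 8 NK cell markers 0 were called in RH (0.546), and 2 rose and 1 fell in Pru (0.924), KLRD1 at 1.27. Of 17 T cell markers 3 rose and 7 fell in Pru (0.121), IL7R at 1.74. Platelet markers had 2 of 7 lower in RH (0.0748) and 3 of 8 lower in Pru (0.157), and erythroid markers had 0 called in either (0.354 and 0.95). Fewer than 3 plasma cell markers and fewer than 3 basophil and mast cell markers passed the filter, so these lists were not tested. GATA2 of the latter rose by 1.22 in Pru. Of 9 fibroblast markers 1 rose and 1 fell in RH (0.577), and of 8 in Pru 2 rose and 1 fell (0.834). COL1A2 was at most 0.172 FPKM in media, at 0.166 FPKM in RH replicate 1, at 3.48 to 4.60 FPKM in the other RH libraries and at 0.809 to 2.96 FPKM in Pru. Other collagens were chosen after their values were seen. COL1A1 did not share the low value of RH replicate 1. It was at 1.24 to 1.94 FPKM in RH with replicate 1 included, against at most 1.02 FPKM in media and 0.9998 FPKM in Pru. COL3A1 was at most at 0.302 and COL6A3 at most at 0.475 FPKM in any library. COL3A1 was at 0.0353 to 0.302 FPKM in Pru, against at most 0.00679 FPKM in media.

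EGR1, an immediate-early gene chosen after its values were seen, was at 4.55 FPKM in RH replicate 1, at 70.2 to 88.3 FPKM in the other RH libraries, at 4.74 to 12.1 FPKM in media and at 6.45 to 14.4 FPKM in Pru.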
